A study of Homo sapiens with 15 samples.

How the data were processed

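Bisulfite PCR products were sequenced from genomic DNA of control cells and cells exposed to hexavalent chromium. The cells were a human lymphoblastoid cell line, a B lymphocyte culture immortalised with Epstein-Barr virus. Bisulfite turns unmethylated cytosine into uracil, which is read as T, and leaves methylated cytosine as C. Per the labels' protocols, DNA was converted, amplified with a panel of bisulfite primers, pooled into a library for each sample and read as paired ends on an Illumina HiSeq instrument. The submitters' processing notes name Trim Galore, BSMAP 2.90, SAMtools 1.3.1 and methylKit, and the genome builds hg19 and GRCh37. The positions in the deposited files lie on 1 sequence, the GenBank reference sequence of the human ribosomal DNA repeat, and not on a chromosome of either build.

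Each deposited file lists cytosines with their sequence context, a read depth, the count of reads with C, the count of reads with T, and the methylated fraction, which the authors gave as the C count over the sum of both counts. Per the file headers the contexts are CG, CHG and CHH, and the lowest listed depth was 10 reads. The counts were used as deposited, and fractions are printed as percent methylation. The parts of the ribosomal DNA unit (upstream sequence, 5' external transcribed spacer, 18S, internal transcribed spacer 1, 5.8S, internal transcribed spacer 2 and 28S) were assigned from the published layout of that GenBank sequence. This layout was added from outside the deposited files, and its boundaries were not checked against the record. Position 1 is the start of the pre-rRNA transcript, and negative positions lie upstream of it.

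The labels put 6 libraries in the control group and 3 libraries each at days 3, 7 and 14. The controls carry replicate numbers 1 to 3 in 2 sets, here called the first and the second set, and both sets formed 1 control group. In the numbering of the titles, the first set stands before day 3 and the second between day 3 and day 7. What this order means is not given. The labels number 3 replicates in each exposed group, although their protocol speaks of fewer biological replicates. No label ties a replicate to a separate culture, so p-values measure the spread between these libraries, which may be technical. The way reads were spread over the tested sites differed between libraries of the same group far beyond counting error (lowest chi-square per degree of freedom 528). No library was therefore taken for a copy of another.

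CpG sites with at least 10 reads in all 15 libraries were tested, which left 851 of the 1388 CpG sites listed in any library. Methylated and unmethylated counts were fitted with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with an effect for each library and a methylation term for each group. All 15 libraries shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. Sites at most 300 bp apart were joined into 9 regions. The mean over a region of log2((methylated + 0.5)/(unmethylated + 0.5)) was tested with limma 3.58.1, adjusted over the 9 regions. The adjusted p-values printed for sites come from edgeR and those for regions from limma, unless another test is named. Percent values of regions and parts were compared by two-sided exact permutation tests over all 84 assignments of 6 and 3 libraries. The smallest p these can give is 0.02381, and with 3 libraries against 3 it is 0.1. Depth, counting errors and intervals concern reads, and PCR reads without molecular identifiers are not independent molecules.

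The design, its tests, the gene lists and the rule for named sites were fixed before the data were examined. Region tests between time points, and exact permutation tests of the 7 parts and of the unconverted shares, were not in that design. Regions past the threshold at any time point are named. For each comparison the rule took up to 5 called sites with the largest rise and up to 5 with the largest fall, at most 2 per region, whose exposed libraries all lay on the same side of the reference mean. Where no site was called, the 3 sites with the lowest unadjusted p were taken. Sites and parts named beyond this rule were chosen after their values were seen.

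Both tests were run on simulated counts made from the control means, the real coverage and the spread between libraries, with 200 of the 851 sites changed, in 5 simulated data sets per comparison. The changed sites were drawn from those of intermediate methylation in controls, so the shares of changed sites called hold for such sites. Spread between libraries was drawn separately for each site, so spread shared by neighbouring sites was not simulated there. For day 3 against control, edgeR called 83.8% of the sites changed by 20 points, 33.6% of those changed by 10 points and 1.137% of unchanged sites. For day 7 against control the shares were 79.6%, 30.4% and 0.584%, and for day 14 against control 81.6%, 31.0% and 0.737%. Between days 14 and 7 they were 67.2%, 20.2% and 0.645%. In 100 simulated data sets per comparison, every site of regions 3, 5 and 8 was raised by 10 points. Of these changed regions, limma on the 9 regions called 80.3% at day 3, 77.3% at day 7 and 79.0% at day 14. Changes in the other regions, and falls, were not simulated. Among unchanged regions, region 6 was called in 80 of 100 data sets at day 7 and in 58 of 100 between days 14 and 7. Its sites read near 1%. Unchanged regions differed between the simulated groups only in coverage. Region 6 held a mean of 0.0221% of CpG reads at day 7, 0.0598% at day 14 and 0.215% in controls. How coverage led to these calls was not tested. The other unchanged regions were called in at most 6 of 100.

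Reads with C at cytosines outside CpG were taken as unconverted, over 1182 such positions with at least 10 reads in all libraries for medians and over every listed position for pooled shares. A local share was computed within 100 bp of each CpG site from at least 3 such positions, and was available for 850 sites. Alternatives covered the coverage minimum, the test, the threshold, the control set, thinning to equal coverage, the replicate number as a block, the joining and averaging of regions, and leaving out each library. A correction for local unconverted reads, a restriction to sites with under 2% unconverted nearby and a minimum of 1000 reads were added after seeing the data. Summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Of 9 gene lists, 1 (ribosomal RNA genes) is covered by these files. The lists of DNA repair, metal and oxidative stress response, tumour suppressors and cell cycle, DNA methylation and chromatin, B cell and lymphocyte identity, markers of other blood cells, imprinted genes, and repeats have 0 measured members.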

Results

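DNA methylation was measured across the 45S ribosomal DNA unit, the tandemly repeated gene that encodes the 18S, 5.8S and 28S ribosomal RNAs, in a human lymphoblastoid cell line treated with 5 µM hexavalent chromium for 24 hours. Control libraries (n = 6) were compared with libraries from days 3, 7 and 14 (n = 3 each), to ask whether methylation changed in the days after the onset of exposure. The libraries held between 28716783 and 95852393 C or T calls over all listed cytosines. Their median coverage at the 851 tested CpG sites lay between 790 and 5449 reads, and single sites held as few as 10 reads. The 9 regions run from position -982, upstream of the transcription start, to position 12931, near the 3' end of the 28S gene.

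In the controls, methylation differed strongly along the unit. The upstream sequence from -982 to -820 was the most methylated region, at 87.0% ± 1.89 (SD, n = 6). The 5' external transcribed spacer averaged 46.0% ± 3.01 (SD, n = 6), the 18S gene 42.7% ± 2.20 and the 28S gene 45.6% ± 2.56. Internal transcribed spacer 1, which separates 18S from 5.8S, was at 57.7% ± 3.58, and internal transcribed spacer 2, which separates 5.8S from 28S, at 15.2% ± 3.15. A stretch of 16 sites in the 28S gene from 8568 to 8666 was nearly unmethylated, at 1.33% ± 0.675 (SD, n = 6). The first and second sets of controls did not differ at any of the 851 sites in edgeR (17 sites at an unadjusted p under 0.05, where chance gives 42.55). The sites with the lowest p between the sets, none past the threshold (edgeR adjusted p = 0.953 for each), were -963 (97.8% in the second set, 93.6% in the first), -839 (80.6% and 89.7%) and 10256 in 28S (30.5% and 42.2%).

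**Figure D1:**
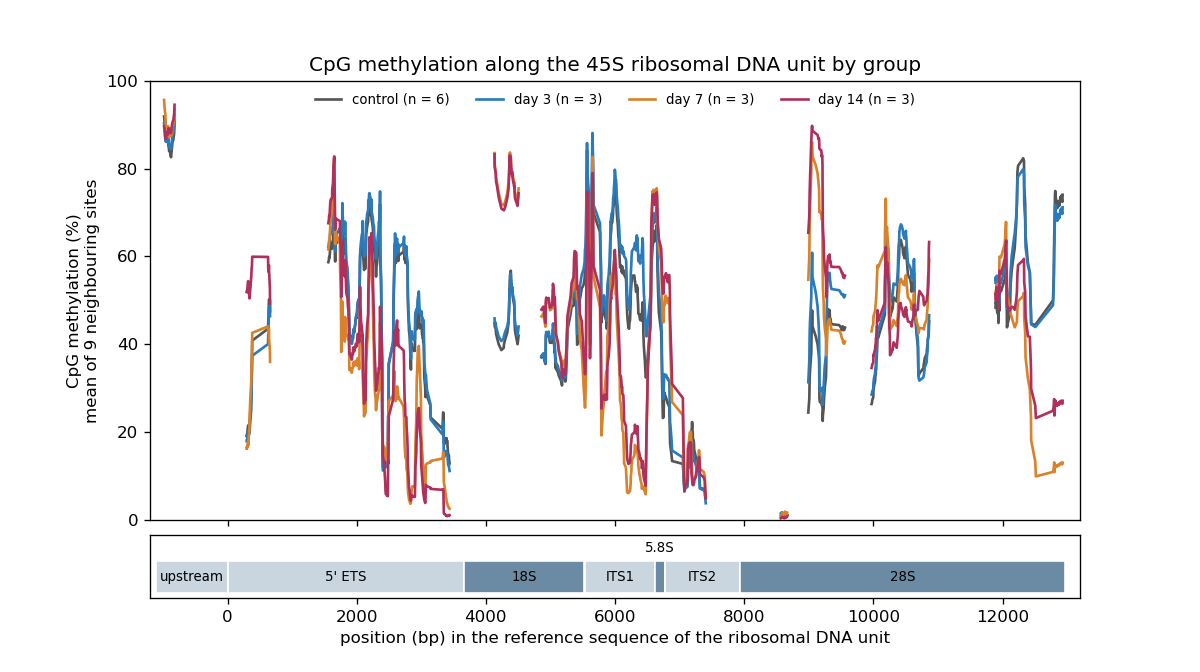
Mean CpG methylation in percent (vertical axis, mean of 9 neighbouring sites within a region) by position in base pairs along the ribosomal DNA unit (horizontal axis), with a line for each group and the parts of the unit drawn to scale below. The control and day 3 lines run mostly close together, while the day 7 and day 14 lines lie above them in the 18S region from 4135 to 4507 and below them over most of the 5' external transcribed spacer from 1561 to 3439 and of the 28S end.

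At day 3, methylation of the ribosomal DNA stayed close to that of the controls. No site in the spacers or in the 18S, 5.8S and 28S genes passed the threshold in edgeR (31 sites at an unadjusted p under 0.05, 0 calls by limma and 0 by a quasi-binomial model). The median absolute difference was 2.84 points over all sites, and 5' external transcribed spacer methylation was 47.2% ± 2.32 (SD, n = 3). The 3 sites with the lowest p, none past the threshold (edgeR adjusted p = 0.929 for each), were -982 upstream (96.2% ± 0.930 against 98.8% ± 0.689 in controls), and 6424 (66.6% ± 6.04 against 50.6% ± 8.55) and 6414 (64.5% ± 5.16 against 49.6% ± 8.57) in internal transcribed spacer 1.

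None of the 9 regions passed at day 3. The 28S region from 8993 to 9561 (region 7) came closest, at 44.1% ± 0.870 (SD, n = 3) against 37.1% ± 4.49 in controls (n = 6), above the control mean in 3 of 3 libraries (limma adjusted p = 0.140, two-sided exact permutation p = 0.02381, 0.2143 after adjustment). The 5.8S gene averaged 47.9% ± 2.26 against 43.7% ± 2.63, and internal transcribed spacer 1 averaged 62.7% ± 1.44 against 57.7% ± 3.58 (exact permutation p = 0.02381 and 0.047619, 0.16667 for both after adjustment over 7 parts). In simulated data of this size, 83.8% of sites of intermediate methylation changed by 20 points were called and 33.6% of those changed by 10 points. Changes of 10 points at single sites could therefore have been missed.

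At day 7, methylation of the ribosomal DNA differed from control at most sites, and in opposite directions in neighbouring parts. The 5' external transcribed spacer fell from 46.0% ± 3.01 (SD, n = 6) to 29.6% ± 3.51 (SD, n = 3), and internal transcribed spacer 1 fell from 57.7% ± 3.58 to 36.1% ± 2.00. The 18S gene rose from 42.7% ± 2.20 to 57.3% ± 5.17, and the 5.8S gene from 43.7% ± 2.63 to 59.0% ± 0.857. Each of these 4 parts had an exact permutation p = 0.02381 (0.041668 after adjustment over 7 parts), with 3 of 3 libraries on 1 side of every control. The 28S gene as a whole stood at 45.3% ± 0.109 against 45.6% ± 2.56 (exact permutation p = 0.85714), with rises and falls inside it.

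Of the 851 sites, 546 passed the threshold at day 7, 190 higher and 356 lower. In the 5' external transcribed spacer 162 of 266 sites were lower and 14 higher, and in internal transcribed spacer 1 129 of 168 were lower and 12 higher. In the 18S gene 57 of 83 sites were higher and 3 lower, and all 17 sites of 5.8S were higher. In 28S 71 of 234 sites were higher and 52 lower. Internal transcribed spacer 2 had 13 higher and 10 lower of 60, and the upstream sequence 6 higher of 23. The ribosomal RNA genes are the single fixed list these sites cover, so the count adjusted over the list alone is the same 546.

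Among the sites taken by the rule, the largest falls lay at the 28S end. Site 12907 went from 83.3% ± 7.19 (SD, n = 6) to 15.5% ± 2.83 (SD, n = 3) and site 12931 from 81.4% ± 6.93 to 14.6% ± 2.61 (edgeR adjusted p = 6.12e-08 and 3.61e-08, at least 4192 reads in every library). Sites 2792 and 2743 of the 5' external transcribed spacer fell by 62.5 and 53.6 points, to 10.1% ± 0.633 and 15.4% ± 13.6, on as few as 20 reads in a library. Site 6263 of internal transcribed spacer 1 fell by 51.3 points to 25.1% ± 8.70. The largest rise, at 2962 in the same 5' spacer, was from 32.0% ± 7.71 to 85.8% ± 13.9, on as few as 15 reads. Sites 4154 and 4159 of 18S rose from 42.2% ± 3.89 and 44.9% ± 3.95 to 81.7% ± 8.85 and 84.1% ± 9.58, on at least 6119 reads. Sites 9055 and 9052 of 28S rose to 87.3% ± 0.971 and 90.7% ± 1.91 from 40.9% ± 19.3 and 45.4% ± 14.3, on as few as 14 and 16 reads. Non-CpG cytosines within 100 bp of them read 43.8% unconverted at day 7 and 9.07% in controls.

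Over regions, 6 of 9 passed at day 7. The 18S region from 4135 to 4507 (region 4) rose from 46.5% ± 3.58 to 77.7% ± 6.20 (limma adjusted p = 9.10e-06) and region 7 of 28S from 37.1% ± 4.49 to 57.0% ± 3.74 (9.10e-06). The 28S end from 11892 to 12931 (region 9) fell from 61.1% ± 5.12 to 36.3% ± 0.599 (5.23e-06), the 5' spacer from 1561 to 3439 (region 3) from 47.2% ± 3.01 to 29.7% ± 3.71 (1.78e-06), and the stretch from 4861 in 18S to 7405 in internal transcribed spacer 2 (region 5) from 45.3% ± 2.66 to 35.4% ± 2.88 (0.00073). Region 5 mixed directions, with 68 of its 297 sites higher and 142 lower. The upstream region also passed (0.0001235), at 90.3% ± 3.38 against 87.0% ± 1.89, but not in the exact permutation test of its percent values (p = 0.1429). Its sites had a median local unconverted share of 17.6% at day 7 and 0.969% in controls. With the local share removed, the same 6 regions passed. With reads summed over each region, 3 of 9 passed (regions 4, 7 and 9), the fall of region 3 no longer passed (-0.475 on the log2 scale) and region 5 turned to a rise (0.29). Region 7 turned to a fall when only its single site with 100 reads in every library was kept (-1.32).

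**Figure D2:**
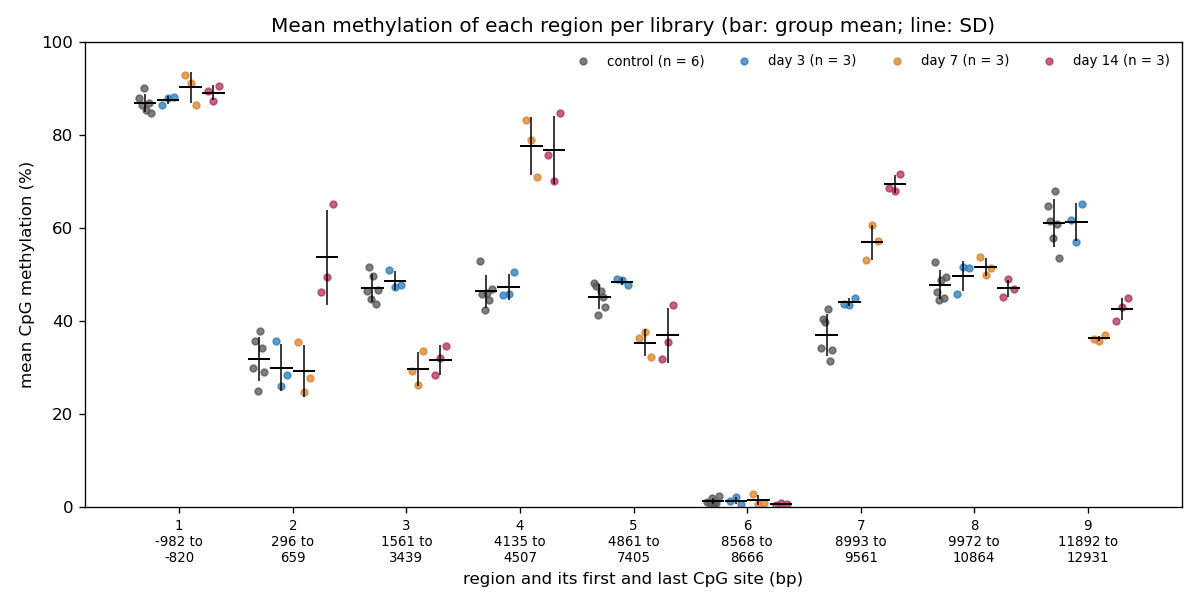
Mean CpG methylation in percent (vertical axis) of the 9 regions (horizontal axis, with first and last site in bp), with a point for each library, a horizontal bar for the group mean and a vertical line for the SD. In region 4 the 6 libraries of days 7 and 14 lie between 70.2% and 84.7%, above every control and day 3 library, and in region 9 they lie below all of them.

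The libraries of days 7 and 14 also differed from the rest outside the CpG sites. Unconverted reads at cytosines outside CpG made up 1.04% ± 0.287 (SD, n = 6) in controls, 1.10% ± 0.247 (SD, n = 3) at day 3, 7.36% ± 1.06 at day 7 and 6.19% ± 1.17 at day 14 (exact permutation p = 0.02381 for both later days against control, 0.035715 after adjustment). Region 7 held at most 0.152% of the CpG reads of a control or day 3 library and at least 10.2% of those of a day 7 or day 14 library. Among the 109 sites with under 2% unconverted nearby in every library, 68 passed at day 7, 46 higher and 22 lower, and 74 at day 14, 54 higher and 20 lower. At day 7, 18S was the only part with a median local unconverted share under 2% (0.839%). The median was 12.1% in internal transcribed spacer 1 and 5.30% in the 5' external transcribed spacer. The limit may therefore leave out more sites of the parts that fell, and where the 109 sites lie was not examined. The labels name no batch. Their protocol combines 12 libraries in a mix, so these 15 needed more than 1, and which libraries shared a mix is not given. No control or day 3 library shares these features, so methylation changes at days 7 and 14 cannot be compared within libraries of like conversion.

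**Figure D3:**
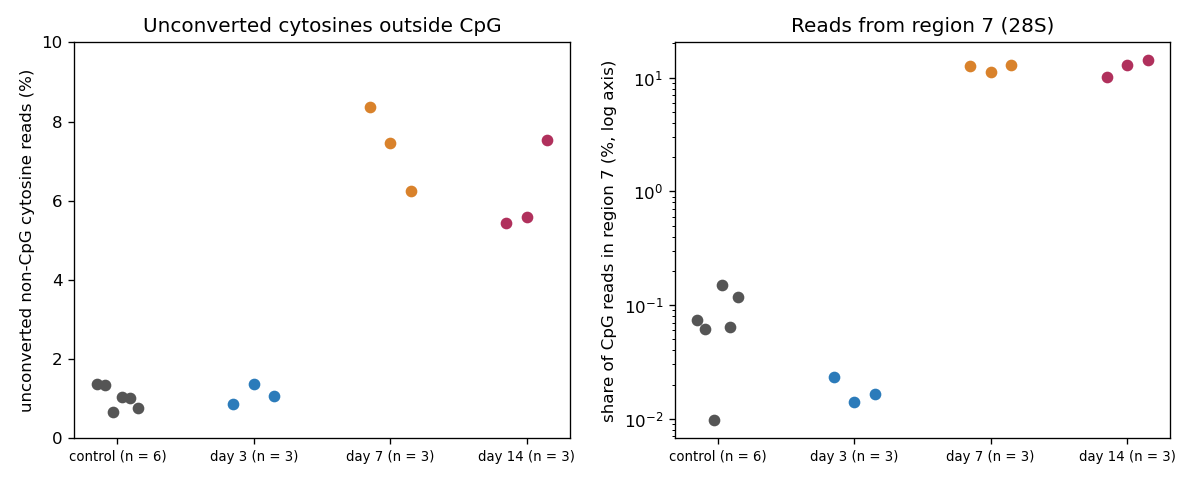
Left, percent of reads unconverted at cytosines outside CpG (vertical axis) for each library (points) by group. Right, share of CpG reads that fell in region 7 of 28S (vertical axis, log scale) for each library. The 6 libraries of days 7 and 14 lie at 5.45% or more unconverted, and the 9 others at 1.38% or less.

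At day 14, the same parts of the ribosomal DNA stood apart from control as at day 7. The 5' external transcribed spacer was at 33.5% ± 3.69 (SD, n = 3), lower than the controls' 46.0% ± 3.01, and internal transcribed spacer 1 was lower at 38.0% ± 6.71 against 57.7% ± 3.58. The 18S gene was higher at 57.9% ± 6.88 against 42.7% ± 2.20, and 5.8S at 61.9% ± 9.52 against 43.7% ± 2.63 (exact permutation p = 0.02381, 0.041668 after adjustment, for each of the 4 parts). Internal transcribed spacer 2 (18.7% ± 2.09) and 28S as a whole (48.1% ± 1.503) did not pass (exact permutation p = 0.16667 and 0.19048).

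At day 14, 604 sites passed, 212 higher and 392 lower. The 5' external transcribed spacer had 145 lower and 37 higher sites of 266, internal transcribed spacer 1 had 152 lower and 12 higher of 168, 18S had 60 higher and 3 lower of 83, 5.8S had 15 higher of 17 and 28S had 76 of each direction among 234. Sites 12907 and 12931 of 28S were at 31.6% ± 6.80 and 29.8% ± 6.52. Sites 2792 and 2804 of the 5' spacer were at 21.0% ± 9.07 and 9.68% ± 4.28, from 72.6% ± 4.73 and 58.3% ± 5.89, on as few as 28 and 12 reads. Site 6254 of internal transcribed spacer 1 fell by 41.7 points to 18.7% ± 9.90. Sites 9164 and 9162 of 28S rose from 26.6% ± 2.895 and 27.4% ± 2.69 to 85.7% ± 3.59 and 86.3% ± 3.73, where 10.7% of nearby non-CpG cytosine reads were unconverted against 1.80% in controls. In 18S, sites 4154 and 4137 rose to 82.8% ± 9.98 and 84.9% ± 9.24. Site 6864 of internal transcribed spacer 2 rose from 20.5% ± 6.77 to 58.3% ± 12.1 on as few as 12 reads, and did not pass after thinning to equal coverage (a log2 ratio difference of 0.971 in place of 2.46). Every site named here had an edgeR adjusted p of 9.70e-05 or less.

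Over regions, 7 of 9 passed at day 14. Region 7 of 28S reached 69.5% ± 1.96 (limma adjusted p = 6.84e-08), region 4 of 18S 76.9% ± 7.31 (1.36e-05) and the 5' spacer from 296 to 659 (region 2) 53.7% ± 10.2 against 31.9% ± 4.80 (0.0004873). Region 3 of the 5' spacer was lower at 31.7% ± 3.21 (7.01e-07), region 9 of 28S at 42.6% ± 2.44 (0.0001819) and region 5 at 37.0% ± 5.96 (0.005582), although region 5 did not pass in the exact permutation test of its percent values (p = 0.07143), and lost its call without replicate 1 of day 14 (-0.429 in place of -0.645 on the log2 scale) and at 100 reads (-0.360). The nearly unmethylated region 6 of 28S passed narrowly (0.04764, 0.657% ± 0.194 against 1.33% ± 0.675; exact permutation p = 0.04762, 0.07143 after adjustment), and leaving out any of the 9 libraries compared ended that call. Region 5 again mixed directions, with 68 of its 297 sites higher and 170 lower. Summing reads ended the call of region 3 (-0.298 on the log2 scale) and turned region 5 to a rise (0.22). The single site of region 7 with 100 reads in every library gave a fall (-1.13).

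Calls at days 7 and 14 overlapped. At both days 152 sites were higher (independent lists of these sizes would share 47.33) and 316 were lower (164), and 0 sites were called in opposite directions. Calls of both days rest on the same controls and are not independent, so an excess over these numbers can come from that. Across sites, the differences from control at days 7 and 14 had r = 0.930 and a covariance of 454, where unchanged groups simulated against the same controls gave 0.332 and 7.24. With the first controls for day 7 and the second for day 14, r was 0.918. Day 3 differences had r = -0.019 with day 7 and r = 0.0097 with day 14. These r values are across sites, which are not independent replicates.

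Direct tests between time points also called sites in these spacers and genes. Between days 7 and 3, 486 sites differed, 128 higher and 358 lower at day 7, with 153 of 266 sites of the 5' spacer and 134 of 168 of internal transcribed spacer 1 lower. Among the 109 sites with under 2% unconverted nearby, 26 differed, 13 higher and 13 lower at day 7. Sites 6412 and 6424 of internal transcribed spacer 1 were at 6.64% ± 0.511 and 7.38% ± 1.49 at day 7 and at 67.9% ± 4.36 and 66.6% ± 6.04 at day 3 (edgeR adjusted p = 1.66e-07 and 2.76e-07). They held as few as 17 and 18 reads in a library. Sites 12907 and 12931 of 28S were lower at day 7 by 64.1 and 63.2 points, and 2792 by 62.4. Sites 2962, 9164, 9173, 4154 and 4135 were higher at day 7, at 85.8%, 71.3%, 74.3%, 81.7% and 87.6% against 33.7%, 27.9%, 32.4%, 43.3% and 49.6%, but 9164 and 9173 did not pass in the quasi-binomial model.

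Between days 14 and 3, 527 sites differed, 143 higher and 384 lower at day 14. The balance turned among the 109 sites with under 2% unconverted nearby, where 37 were higher and 13 lower. This turn cannot be told apart from a change in the parts counted, which the limit may bring. In internal transcribed spacer 1, 153 of 168 sites were lower, among them 6435 (10.8% ± 3.49 against 64.6% ± 7.70) and 6437 (10.7% ± 5.00 against 63.8% ± 6.63). Sites 6435 and 6437 held as few as 15 and 16 reads in a library. Sites 2792 and 2804 of the 5' spacer were at 21.0% and 9.68% against 72.5% and 59.5%, and 12907 of 28S at 31.6% against 79.6%. Sites 9164 and 9166 of 28S were higher at day 14, at 85.7% and 84.5% against 27.9% and 28.8%, although neither passed in the quasi-binomial model, as were 4154 and 4137 of 18S, at 82.8% and 84.9% against 43.3% and 46.6%. Site 296 of the 5' spacer was at 57.8% ± 17.5 at day 14 and 19.8% ± 5.08 at day 3.

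Days 14 and 7 differed at fewer sites. In 28S 72 sites were higher and 5 lower at day 14, and in the 5' external transcribed spacer 35 were higher, 12 of them in region 2, and 31 lower, all in region 3. Region 2 of the 5' spacer went from 29.4% ± 5.61 (SD, n = 3) at day 7 to 53.7% ± 10.2 at day 14, region 7 of 28S from 57.0% ± 3.74 to 69.5% ± 1.96, and the upstream region from 90.3% ± 3.38 to 89.2% ± 1.57 (limma adjusted p = 0.001666 for each). The exact permutation p of their percent values was 0.1, 0.1 and 0.7, where 3 libraries against 3 allow none under 0.1. Sites 341 and 314 in region 2 rose by 39.4 and 38.1 points, to 59.3% ± 14.1 and 54.4% ± 16.9. Sites 12517, 9236 and 9231 of 28S were higher at day 14, at 60.5% ± 19.2, 62.8% ± 2.70 and 78.8% ± 4.21. Site 12517 held as few as 13 reads in a library. Sites 2962 and 2568 of the 5' spacer were lower at day 14, at 47.8% ± 7.14 and 3.86% ± 1.87, as were 12041, 10185 and 10179 of 28S, at 49.9% ± 3.19, 30.4% ± 8.56 and 42.7% ± 10.6. The local unconverted share was lower at day 14 at these 5 sites as well, at 4.01% against 9.21%, 11.6% against 17.2%, 3.33% against 7.69%, and 3.32% against 14% at both 10185 and 10179. With that share removed, 2568, 10185 and 10179 no longer passed.

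In all, 158 sites differed between days 14 and 7, 118 higher and 40 lower at day 14. The count was 4 when only these 6 libraries were fitted, with none of the sites named here among them, 57 without replicate 1 of day 7, 61 without replicate 3 of day 14 (29 higher and 32 lower), 49 at 100 reads (48 higher and 1 lower) and 77 without replicate 2 of day 14. Any difference among the 4 groups was found at 646 of the 851 sites.

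The mean over the whole panel followed the sites that fell. It was 46.8% ± 2.28 (SD, n = 6) in controls, 49.0% ± 0.528 (SD, n = 3) at day 3, 39.4% ± 0.527 at day 7 and 41.8% ± 3.79 at day 14. The exact permutation p against control was 0.095238 at day 3, 0.02381 at day 7 and 0.095238 at day 14 (0.07143 at day 7 after adjustment over 3 comparisons). Averaged over the 9 regions in place of sites, the mean was higher than control by 0.427 points at day 7 (exact permutation p = 0.80952) and by 4.81 points at day 14 (exact permutation p = 0.02381). With reads summed over sites, the difference from control was 0.994 points at day 3 and -1.45 points at day 14 (exact permutation p = 0.7619 and 0.66667).

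Libraries of a group differed at a typical site by an SD of 4.53 points in controls (n = 6), 3.24 points at day 3, 4.80 points at day 7 and 4.58 points at day 14 (n = 3 each). Counting error alone gives 1.25 points in controls and 0.683 points at day 7. Over sites, r between pairs of control and day 3 libraries lay between 0.932 and 0.975, between pairs of day 7 and day 14 libraries between 0.817 and 0.964, and across these 2 sets between 0.449 and 0.649.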

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

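The tests of incomplete conversion and of library preparation in this part were chosen after the results were seen. Thinning to equal coverage was set before the data were examined, but its use here against unequal depth was chosen after the results were seen. The tests of drift in single libraries and of other splits were set before their results were seen. Direct tests set days 7 and 14 apart from day 3 at 486 and 527 sites of the ribosomal DNA and in 6 and 6 of the 9 regions. They set day 14 apart from day 7 at 158 sites and in 3 regions. Unconverted cytosines outside CpG, which the tests of CpG counts as deposited do not use, stood at 7.36% at day 7 and 6.19% at day 14, above the 1.04% of controls. A further signal lay in positions left out of the tests, since 24 CpG sites between 8060 and 12725 were listed in all 6 libraries of days 7 and 14 and in none of the 9 others. In the other direction, 12 sites between 7523 and 7706 were listed in all 9 control and day 3 libraries and in none of the 6.

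The falls in the 5' external transcribed spacer, internal transcribed spacer 1 and the 28S end would need fewer unconverted reads near these sites than in controls, if incomplete bisulfite conversion were their cause. At the 356 lower sites of day 7 the median fall was -28.6 points (quartiles -35.6 and -16.0), and the local unconverted share was higher than in controls by a median of 3.01 points (quartiles 0.561 and 6.88). At the 392 lower sites of day 14 the share was higher by a median of 1.65 points (quartiles -0.0894 and 4.85), against a median fall of -20.8 points. The largest drop of the share at any of these sites was 0.893 points at day 7 and 1.7 points at day 14, so incomplete conversion is argued against. The bound was loosened once: a first one, a lower quartile above 0, was missed at day 14. What else set these sites apart stays open.

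The rises in 18S, 5.8S and region 7 of 28S go in the direction that unconverted reads would give. Outside region 7, the median rise at day 7 was 14.99 points before and 11.9 points after the local unconverted share was removed (quartiles 7.67 and 21.8, 159 sites). In region 7 it was 42.0 before and 38.5 after (quartiles 31.6 and 40.4, 30 sites), and of all higher sites 164 of 189 were still called. Incomplete conversion is therefore not the whole cause, and a part of the rise may come from it. The 18S gene rose from 42.7% ± 2.20 to 57.3% ± 5.17 at day 7. Its median local unconverted share was 0.839% at day 7 and 0.303% in controls, which argues against conversion as the main source of the rise in 18S. Reads whose conversion failed along the whole molecule were not tested, since the files give no single reads.

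The 6 libraries of days 7 and 14 stand apart from the 9 others along most of the unit. Unequal depth is argued against, since 474 of the 546 day 7 calls were found again with every site thinned to equal coverage. Drift of single libraries from few template molecules is argued against too, since the 3 day 14 libraries all lay on the day 7 side of the control mean at 95.8% of the day 7 calls and at 55.1% of the sites not called, while the 3 day 3 libraries all lay there at 20.1% of the same calls. A different library preparation and a late response to chromium cannot be told apart, because no control library shows the conversion and product mix of the day 7 and day 14 libraries. The labels give no day for any control, so time in culture cannot be told apart from exposure either. The lowest read share of region 7 among those 6 libraries was 67.1 times the highest among the others. The shares of region 6 did not overlap either. Those of region 9 overlapped, but its median reads per site did not (at most 3101.5 in the 9 and at least 9938.5 in the 6). In regions 3, 4 and 5 both measures overlapped. A late response to chromium was not tested by any comparison free of this difference.

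Other splits of the same libraries show whether a chance assignment of these libraries gives as many calls. For day 7 against control, 1 of 84 splits (the real one) gave 546 sites or more, and the highest other gave 69. For day 14, 1 of 84 gave 604 or more, and the highest other gave 0. For any difference among the groups, 1 of 100 drawn splits gave 646 or more, and the highest other gave 145. For regions, 1 of 84 splits gave the 6 of day 7 (highest other 1) and 1 of 84 the 7 of day 14 (highest other 2). For these 5 counts, no other split tried reached the real count. The 5 counts share controls and data, so they are not separate tests. Libraries that share a culture or a preparation could give the same result, so chance between cultures or preparations is not excluded. For day 3, 84 of 84 splits gave at least the 0 sites found (highest other 1) and 84 of 84 at least the 0 regions (highest other 1), which a count of 0 gives in any case, so these splits tell nothing about day 3. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real counts and the highest others were 486 and 0 between days 7 and 3 (1 split as large), 527 and 0 between days 14 and 3 (1), 158 and 102 between days 14 and 7 (1), and 0 and 0 between the control sets (10).

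Among controls, 2 single values lay far from the other 5. Site 9162 of 28S read 32.5% in replicate 2 of the first set, with the nearest other control at 27.7%, and site 12907 of 28S read 69.6% in replicate 3 of the second set, with the nearest at 83.2%. Of 52 values examined in this way, chance gives about 2.6.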

How the results depend on the processing

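The corrections, the 2% limit and the 1000-read minimum were added after seeing the data. Day 3 had 0 sites and 0 regions under every alternative run. Stricter site filters tested fewer sites, and in most comparisons called a smaller share of them. A minimum of 100 reads (493 sites) gave 334 at day 7, 344 at day 14, 371 for any difference, 295 between days 7 and 3, 308 between days 14 and 3 and 49 between days 14 and 7. A minimum of 1000 reads (320 sites) gave 226, 219, 235, 170, 190 and 32. Sites with under 2% unconverted nearby (109 sites) gave 68, 74, 78, 26, 50 and 16. Between days 14 and 7, the count was also 36 at a threshold of 0.01, 83 with limma on percent, 40 after thinning and 4 with only the groups compared; leaving out a library gave 57 to 208. The cause was not tested. Against the first controls alone 492 sites passed at day 7 and 546 at day 14, and against the second alone 467 and 471. Leaving out a library gave 471 to 557 sites at day 7, 498 to 602 at day 14, 588 to 684 for any difference, 413 to 514 between days 7 and 3, and 424 to 508 between days 14 and 3.

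Regions called numbered 3 at day 7 with reads summed, and at day 14 numbered 3 with gaps of 1000 bp and 4 at 100 reads; left-out libraries gave 6 to 7 and 5 to 6. Summed reads, which weight the deeply read sites, turned region 5 to 0.287 at day 7 and 0.220 at day 14 (log2). At 100 reads region 7 keeps 1 site and turned to -1.32 and -1.13. The panel mean at day 7, -7.40 points, was 0.427 averaged over regions, -7.78 and -7.03 with the first and second controls (neither can pass with 3 against 3), and -7.96 to -6.96 without single libraries, where leaving out a day 7 library allows no p under 0.071429. At day 14, -4.95 points became 4.81 over regions, -7.27 at 100 reads and -1.45 with reads summed, and at day 3 2.27 points became 0.994 with reads summed and 1.49 over regions. At day 3 and day 14 left-out libraries gave 1.71 to 2.72 and -6.99 to -3.24. Named sites that were called kept their direction under each alternative that still tested them. Their calls were lost 30 times under the alternatives (524 kept), and 21 times with a library left out (339 kept). A named site that a stricter filter removed was not counted as kept or lost.

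The correlation of day 3 with day 7 differences was 0.0445 on the log2 scale and -0.0723 with exchanged control sets; that of day 3 with day 14 was 0.132 and -0.0518, and that of day 7 with day 14 was 0.864 on the log2 scale. With the replicate number as a block, the counts were 527 at day 7, 598 at day 14, 623 for any difference, 462, 503 and 147 between time points and 0 at day 3 and between control sets; the panel mean difference at day 7 stayed -7.40 but its exact permutation p became 0.074074, the smallest that the block allows. The numbers do not pair the libraries: 4 of 27 same-numbered pairs had r over 0.1 (-0.27 to 0.17), and 5 of 15 libraries correlated best with their own number.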

Other observations

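Internal transcribed spacer 2 and the 28S stretch from 9972 to 10864 (region 8) did not pass as wholes at days 7 or 14. The spacer was at 15.2% ± 3.15 (SD, n = 6) in controls, 18.5% ± 5.17 (SD, n = 3) at day 7 and 18.7% ± 2.09 at day 14 (exact permutation p = 0.21429 and 0.16667). Region 8 was at 47.8% ± 3.13, 51.7% ± 1.94 and 47.1% ± 1.89 (limma adjusted p = 0.144 at day 7 and 0.7602 at day 14).

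The upstream sequence had the highest local unconverted share among the parts at days 7 and 14, with medians of 17.6% and 16.0% against 0.969% in controls. In 18S these medians were 0.839% and 0.681% against 0.303%.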
